A study of Glycine max with 6 samples.

How the data were processed

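RNA from soybean leaves was measured on 6 Affymetrix soybean arrays, 3 of control pots and 3 of rust-inoculated pots. Per the labels' protocols, plants were kept at 28 °C by day and 20 °C by night with 14 h of light and 10 h of darkness. Inoculation was by rubbing rusted leaves on the upper leaf surface, and biotin-labelled cRNA was made from 6 µg of total RNA. The deposited values are intensity values on a linear scale, 1 per probe set, from 2.83 to 82901. Per the submitters' processing notes, GCOS and GCRMA were used, with no version or role stated. GCRMA corrects background by probe sequence, normalizes between arrays by quantiles and summarises probes on the log2 scale. How the deposited linear values were reached from there is not given in the sources used here. The scanner files were not used here. A normalization that makes arrays alike in distribution can hide a global shift, and background correction compresses probe sets near the floor.

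Samples were grouped by their titles, which their source names match. The treatment text in each sample's record is that of the other group, and it was not used for grouping. The labels call the samples biological replicates and the design names 3 pots per group, without saying which array came from which pot. No label says that equal numbers share anything.

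Values were transformed as log2(intensity + 16), so that fold changes are on that scale and understate changes of dim probe sets. Each of 37593 soybean probe sets was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group as the only term, all 6 arrays, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05. An exact test of 3 against 3 arrays cannot go below a two-sided p of 0.1, so tests of single values were not run. The 61170 probe sets of the file also include 15820 for Phytophthora sojae, 7530 for the cyst nematode, 135 array controls and ribosomal RNA probe sets of soybean (48) and P. sojae (44). The 95th percentile of the means of the P. sojae and nematode probe sets, 4.45, served as the background level.

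The platform table named 9047 probe sets, 8677 with 1 gene and 370 with several. Another 28546 soybean probe sets were unlisted there and stay unnamed. Of those with 1 gene, 8652 matched a gene of the RefSeq annotation of Glycine_max_v4.0, which was used for names and synonyms only. They stand for 6029 genes, of which 1003 have a symbol other than a LOC number. The array has no genome build, so no coordinates are given.

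A total of 30 gene lists, the tests, the alternatives and the rule for named genes were written before the data were examined. Because the annotation has symbols and synonyms without descriptions, 15 lists had at least 3 probe sets and were tested and 15 had too few. The latter were lignin enzymes, class III peroxidases, antioxidant enzymes, NBS-LRR proteins, receptor-like kinases, photosystems, chlorophyll and carotenoid synthesis, wall remodelling, histones and cell cycle, ribosomal proteins, protease inhibitors, clock genes, abscisic acid, auxin response and reference genes. A further 31 lists of symbols were written after the annotation and the correlations between arrays were seen and before the groups were compared. Lists were tested with camera at a preset correlation of 0.01, adjusted over the lists of the same kind, with an estimated correlation and fry as alternatives. A departure of an array is its log2 value minus the median of the other 5 arrays. A list's median departure was ranked among 10000 random lists of the same size matched on mean level, as a description of that array.

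The rule for named genes took up to 15 probe sets in each direction past the threshold, with 1 gene, groups that do not overlap and a mean above the background level, 1 probe set per gene (the brightest), and up to 4 such members of each list. If none passed, it took the 10 with the lowest unadjusted p in each direction, as values with no call and without the condition on overlap, and this was the case. All other genes were named after their values were seen.

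The alternatives were quantile normalization, centring of arrays on their medians, 2 filters on dim probe sets, array weights, a trended and robust variance prior, the replicate number as a block, pseudocounts of 1 and 64, an unmoderated two-sample test, testing all probe sets except array controls, averaging the probe sets of a gene, thresholds of 0.1 and 0.01, and leaving out each array. Another 3 were added after the data were seen, namely log2 with no pseudocount, the 4 arrays of replicates 1 and 2 with the replicate block, and the symbol lists. Leaving out an array leaves 5, and limma pools the spread over both groups. The fit was tested on simulated data with the real means and spreads, in which 200 of 37593 probe sets were changed. These were drawn from probe sets with a mean more than 2 log2 units above the background level. The fit recovered 0%, 21%, 49% and 56.5% of those changed 2-, 4-, 8- and 16-fold, and called 0, 3, 13 and 7 unchanged probe sets.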

Results

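Leaves of the soybean cultivar 5601T were profiled 72 h after plants were exposed to Phakopsora pachyrhizi, the rust fungus that causes Asian soybean rust. The plants were 3 weeks old and at the V2 stage, in which the first trifoliate leaves are open. They stood in 6 pots of 4 l with 3 plants each, of which 3 pots were inoculated. The groups were 3 control arrays and 3 rust-inoculated arrays, numbered as replicates 1 to 3 within each group. The question was which soybean transcripts differ in level between rust-inoculated and uninoculated leaves at this time. Titles and source names of the samples agree on which arrays were controls. The treatment text stored with each sample describes the procedure of the opposite group. Every direction given here follows the titles and source names, and would turn around if the treatment text were right. According to that text the controls were kept in an adjacent growth chamber, so chamber and inoculation cannot be told apart in this design. Inoculation was done by rubbing leaves, and no label says whether control leaves were rubbed without rust, so an effect of rubbing cannot be told apart from infection either.

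The array carries 37593 soybean probe sets, sets of short probes that report 1 or more related transcripts. Between 32358 and 32769 of them (86.1% to 87.2%) lay above the level that bounds 95% of the probe sets made for other organisms. The median soybean intensity ran from 142 on control replicate 3 to 195 on control replicate 2. The number of arrays limits the precision. The median standard error of a group difference was 0.28 on the log2 scale among the 32972 probe sets with a mean above that level, and the median 95% confidence interval reached 0.73 to either side.

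Control replicate 3 differed from the other 5 arrays far more than any of these differed among themselves. Its correlation with them was 0.845 to 0.877, against 0.959 to 0.987 among the other 5, across the 32972 soybean probe sets with a mean above the background level. On it, 2740 probe sets lay more than 2-fold above the median of the other 5 arrays and 5548 lay more than 2-fold below. The same counts on the remaining arrays were 651 to 1154 above and 237 to 1501 below. The first principal component of these 32972 probe sets held 65.9% of the variance and placed control replicate 3 at 188, with the others between -52.1 and -25.9. The second held 18.5% and placed the arrays of replicate 1 of both groups, at 63.6 and 54.4, away from control replicate 2 and rust-inoculated replicates 2 and 3, at -49.4 to -30.2.

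**Figure D1:**
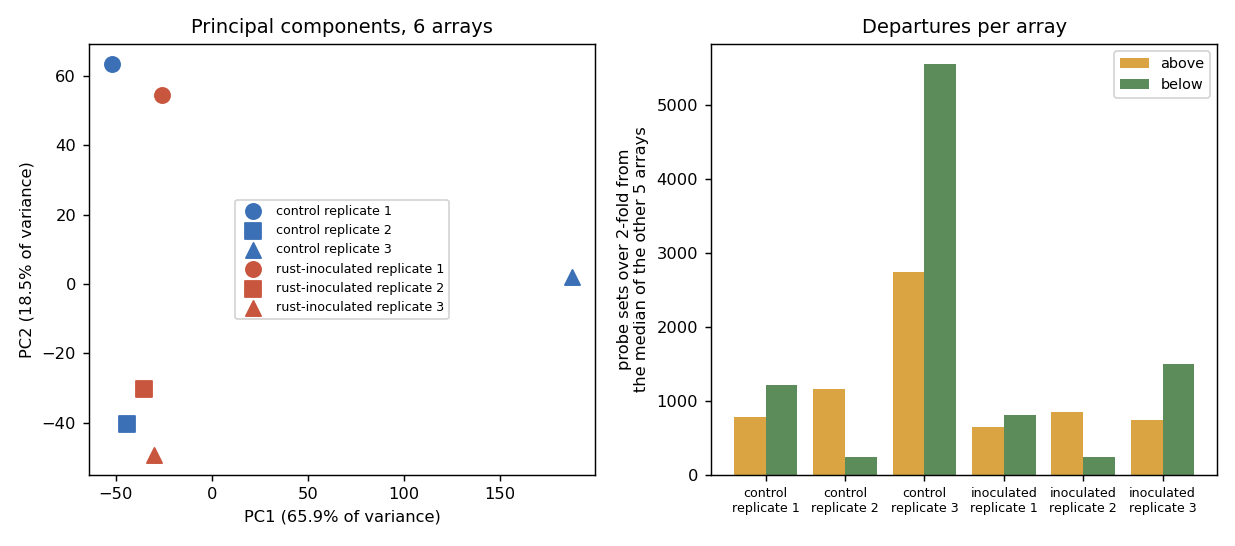
Left, the 6 arrays on the first and second principal components of the log2 values, in component units, of the soybean probe sets with a mean above the background level. There is 1 point per array, with colour for group and shape for replicate number. Right, the number of probe sets on each array that lay more than 2-fold above or below the median of the other 5 arrays, where control replicate 3 reached 2740 above and 5548 below.

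Lipoxygenase transcripts as a list were lower and heat shock protein transcripts as a list higher in the rust-inoculated leaves by camera with a preset correlation of 0.01 between genes, while no single probe set passed the threshold. Both calls were lost with an estimated correlation (adjusted p = 0.455 for each). Fry, which is a separate test, called neither list (adjusted p = 0.358 and 0.753). The median log2 difference was -0.36 over the 25 probe sets of the jasmonate and lipoxygenase list and 0.35 over the 18 probe sets of the heat shock list. Of 37593 soybean probe sets, 0 passed an adjusted p of 0.05 in limma, and the lowest adjusted p was 0.99999. At an unadjusted p under 0.05 there were 219 probe sets, 105 higher and 114 lower after inoculation, where chance alone gives 1879.6. Of these, 10 differed at least 2-fold, 8 higher and 2 lower. The unmoderated two-sample test also gave 0, with 173 probe sets at an unadjusted p under 0.05. All 3 inoculated values lay above all 3 control values for 282 probe sets (0.75%) and below them for 540 (1.44%), where chance gives 5% each way. Without control replicate 3 there were again 0 probe sets past the threshold, with 670 at an unadjusted p under 0.05. The unadjusted count was 787 without control replicate 1, 622 without control replicate 2, 535 without rust-inoculated replicate 1, and 248 and 322 without rust-inoculated replicates 2 and 3.

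Only large shifts were recovered in trials. When known shifts were added to the inoculated arrays for 200 probe sets, limma recovered 0 of those shifted 2-fold, 26 (13%) of those shifted 4-fold, 63 (31.5%) at 8-fold and 107 (53.5%) at 16-fold. Without control replicate 3, the same shifts were recovered for 0, 5, 35 and 94 of the 200. The 200 were drawn from probe sets with a mean more than 2 log2 units above the background level. The rates hold for such probe sets and for this number changed.

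Of the 25 probe sets of the jasmonate and lipoxygenase list, which stand for 9 genes, 22 had a lower mean in the inoculated leaves. Lipoxygenases add oxygen to polyunsaturated fatty acids, a reaction that also opens the synthesis of jasmonates. The list's camera test gave an adjusted p of 3.73e-08 with a preset correlation of 0.01 between genes, and an adjusted p of 0.455 with an estimated correlation. None passed over all probe sets, and 0 passed when adjusted over the list alone, where the lowest adjusted p was 0.0777. LOX9 had 3 of its 5 probe sets with all inoculated values below all control values, at log2 differences of -0.58 (SE 0.14), -0.55 (SE 0.098) and -0.61 (SE 0.14). These were chosen after their values were seen. Its brightest probe set differed by -0.36 (SE 0.29), from 13.75 ± 0.43 to 13.38 ± 0.32 (log2, SD, n = 3). The brightest probe set of LOC547835, which carries the synonym loxA, differed by -0.80 (SE 0.65), and that of LOXB1 by -0.13 (SE 0.094). On control replicate 3 the list's median lay 0.251 above the median of the other 5 arrays and on control replicate 1 it lay 0.525 above. On control replicate 2 it was -0.00371, and on the inoculated arrays it was -0.0679, -0.0871 and -0.206. Without control replicate 3 the list's median was -0.28 with an adjusted p of 0.000233, and without control replicate 1 it was -0.18 with an adjusted p of 0.00281, inside a range of 1.57e-10 to 0.00281 over the arrays left out.

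Heat shock proteins, chaperones that bind unfolded proteins, had higher means after inoculation in 16 of 18 probe sets, which stand for 6 genes. The camera test gave an adjusted p of 1.37e-07 with the preset correlation and an adjusted p of 0.455 with an estimated correlation, and 0 members passed over all probe sets or when adjusted over the list alone. HSP22.3, a small heat shock protein, differed by 2.07 (SE 0.84), or 4.2-fold, with all 3 inoculated values above all 3 control values (10.06, 12.40 and 11.14 against 7.90, 9.75 and 9.73). HSP22.5 differed by 3.20 (SE 1.6), HSP23.9 by 0.60 (SE 0.30) and HSP90A1 by 0.38 (SE 0.36), each at its brightest probe set. None of these 4 passed the threshold. The list's median lay 0.606 below the median of the other arrays on control replicate 1 and 0.452 below on control replicate 3, and it was 0.227 on control replicate 2. On the inoculated arrays it was -0.245, 0.508 and 0.35 for replicates 1, 2 and 3. The list's median was 0.34 without control replicate 3, with an adjusted p of 0.000714. Over the 6 arrays left out in turn, it lay between 0.25 and 0.56, with adjusted p between 1.87e-09 and 0.00907.

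**Figure D2:**
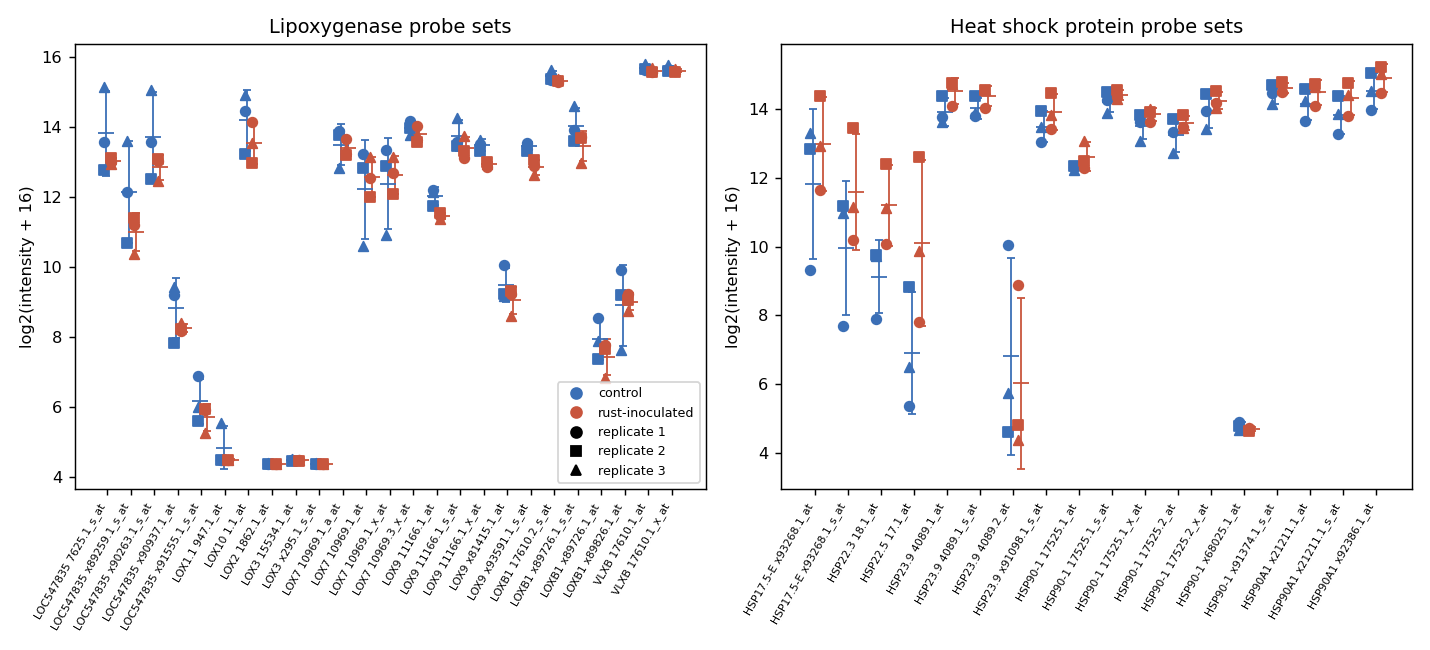
Log2 of intensity plus 16 of each probe set of the jasmonate and lipoxygenase list (left) and of the heat shock protein list (right), named by gene and probe set. Points are the 3 control and 3 rust-inoculated arrays, with shape for replicate number, and the bars give the mean and 1 SD. Of the lipoxygenase probe sets 22 of 25 had a lower inoculated mean, and of the heat shock probe sets 16 of 18 had a higher one.

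Aquaporins and Rubisco activase were the other lists called by camera with the preset correlation. Aquaporins, membrane channels for water, had 31 probe sets of 16 genes, of which 20 had a higher inoculated mean, with a median difference of 0.27 and an adjusted p of 0.00642 (adjusted p = 0.588 with an estimated correlation). Control replicate 3 was low for this list, at -0.608 against the other 5 arrays, with 13 of 31 probe sets more than 2-fold below them. PIP1-6 read 9.67 on that array and 12.71 to 13.69 on the others. Without control replicate 3 the median was -0.058 with an adjusted p of 0.882, and without rust-inoculated replicate 2 the adjusted p was 0.166, so the call ended in both cases. The Calvin cycle and Rubisco list held 4 probe sets, all of RCA11 and RCA14, which encode Rubisco activase. All 4 had a higher inoculated mean, with a median of 0.12 and an adjusted p of 0.0379 (adjusted p = 0.547 with an estimated correlation). This call held without control replicate 1, at an adjusted p of 0.0264. It ended without each of the other 5 arrays, at adjusted p of 0.0582 and 0.558 without control replicates 2 and 3, and 0.0837, 0.125 and 0.0669 without rust-inoculated replicates 1, 2 and 3. When the probe sets of each gene were averaged, the lipoxygenase and heat shock lists were called (adjusted p 0.00261 and 0.00197) and the aquaporins and Rubisco activase were not (0.0941 and 0.22).

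Pathogenesis-related proteins, antimicrobial proteins that many plants make on infection, had a median difference of 0.096 over 7 probe sets, 4 higher and 3 lower, and the list was not called (adjusted p 0.251). PR1-7 was 8.96 ± 3.12 in controls and 9.05 ± 1.54 in inoculated leaves (log2, SD, n = 3), and PR-10 was 9.85 ± 2.39 and 9.71 ± 1.91. The spread lay between arrays within each group. PR1-7 read 5.76, 9.10 and 12.01 on control replicates 1, 2 and 3, and 7.27, 9.90 and 9.98 on inoculated replicates 1, 2 and 3. Relative to the other 5 arrays, the list's median was -1.68, 0.105 and 1.23 on the controls and -0.724, 1.04 and 0.509 on the inoculated arrays. Without control replicate 3 the list's median was 0.79, higher after inoculation, with an adjusted p of 0.0108. Without rust-inoculated replicate 1 it was 0.99 with an adjusted p of 0.00329, and without control replicate 1 it was -0.78 with an adjusted p of 0.288. These camera values are at the preset correlation. With all arrays, the estimated correlation gave this list an adjusted p of 0.723.

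The lists of secondary metabolism were not called. Phenylpropanoid core enzymes, which feed lignin and flavonoid synthesis, had a median of -0.047 over 12 probe sets (adjusted p 0.604), and the brightest probe set of PAL2.1, a phenylalanine ammonia-lyase, was 13.71 in controls and 13.73 in inoculated leaves. Flavonoid and isoflavonoid enzymes had a median of -0.092 over 35 probe sets (adjusted p 0.251), with CHI1A, a chalcone isomerase, at -0.53 (SE 0.29). On control replicate 3 this list's median was 0.549 above the other 5 arrays. The list was lower at an adjusted p of 0.000967 without control replicate 1 and 0.0246 without rust-inoculated replicate 3, while without control replicate 3 the camera test turned to higher with no call (adjusted p 0.0617, median -0.022). UDP-glycosyltransferases, which attach sugars to small molecules, had a median of -0.32 over 8 probe sets (adjusted p 0.0707). The adjusted p was 0.007 without rust-inoculated replicate 3, and 0.549 with a median of -0.019 without control replicate 3. Cytochrome P450s had a median of -0.031 over 70 probe sets (adjusted p 0.251). The pattern for that list had also taken 16 probe sets of cyclophilins, and the 53 probe sets of P450 symbols without these had a median of -0.082 (adjusted p 0.237).

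Glutathione S-transferases, detoxifying enzymes, had a median of -0.09 over 58 probe sets, 18 higher and 40 lower (adjusted p 0.251). Control replicate 3 was high for this list, at 0.581. Without it the camera test turned to higher after inoculation (adjusted p 0.00601, median 0.053), and without control replicate 1 it was lower (adjusted p 0.00176, median -0.28). WRKY transcription factors, many of which act in defence signalling, had a median of -0.065 over 104 probe sets (adjusted p 0.251). WRKY63 differed by 0.80 (SE 0.36) and WRKY9 by -0.98 (SE 0.45). The WRKY list was lower at an adjusted p of 6.16e-06 without control replicate 1 and 0.007 without rust-inoculated replicate 3, while without control replicate 3 its test turned to higher with no call (adjusted p 0.0844, median 0.0068). Ethylene synthesis and ERF factors had a median of -0.025 over 8 probe sets (adjusted p 0.306, and 0.0479 without rust-inoculated replicate 2). Salicylate and immune regulators had a median of 0.15, with 7 of 8 probe sets higher (adjusted p 0.0719). EDS1-2 and PAD4, partners in basal immunity, differed by 0.28 (SE 0.25) and 0.39 (SE 0.53). That list was higher at an adjusted p of 0.0408 without control replicate 2 and 0.0479 without rust-inoculated replicate 2, while without control replicate 3 its median was -0.013 with an adjusted p of 0.882. The list of vegetative storage proteins, in which 4 of 15 probe sets are those of LOXB1 and also belong to the lipoxygenase list, had a median of -0.007 (adjusted p 0.251). Without control replicate 3 its median was -0.25 with an adjusted p of 0.00279. The markers of root, nodule and seed had 3 probe sets near the background level and a median of -0.029 (adjusted p 0.366). In each of these lists 0 members passed over all probe sets, and 0 passed when adjusted over the list alone. With an estimated correlation, 0 of the 15 lists were called.

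The genes named by single probe set are those with the lowest unadjusted p in each direction, since none passed the threshold, and they are given as values with no call. Among the 10 higher after inoculation, LOC100527213 differed most, from 13.21 ± 0.36 to 14.10 ± 0.14 (log2, SD, n = 3), a difference of 0.90 (95% confidence interval 0.35 to 1.44) or 1.86-fold. The others were LOC100800677 (0.20), LOC100500629 (0.38), LOC106795441 (0.36), LOC100811638 (0.37), LOC100806523 (0.30), LOC100777835 (0.32), LOC100306007 (0.18), SOYCTA (0.30) and LOC100805970 (0.42), each as a log2 difference. Among the 10 lower, GSTU58, a glutathione S-transferase of the tau class, differed by -0.98 (95% confidence interval -1.89 to -0.066), from 7.11 ± 0.49 to 6.13 ± 0.42. Its groups overlapped, with 6.61 on rust-inoculated replicate 1 and 6.59 on control replicate 2. LOC100527430 differed by -0.97 (95% confidence interval -1.64 to -0.31), from 8.43 ± 0.12 to 7.46 ± 0.46. The others were LOC100527706 (-0.45), LOC100789771 (-0.17), LOC100499721 (-0.36), the cyclophilin CYP62 (-0.16), LOC100803129 (-0.25), LOC100805422 (-0.23), GOS12 (-0.22), whose name is that of a Golgi SNARE protein, and LOC100812618 (-0.32). Other probe sets of the same gene differed in places. Those of LOC100306007 and LOC100812618 included 1 of the opposite sign, at -0.063 and 0.064. The other probe set of SOYCTA gave 0.086, and the other probe sets of LOC100527213 gave 0.90, 1.33 and, near background, 0.024. All adjusted p were 1 for the probe sets named by the rule.

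**Figure D3:**
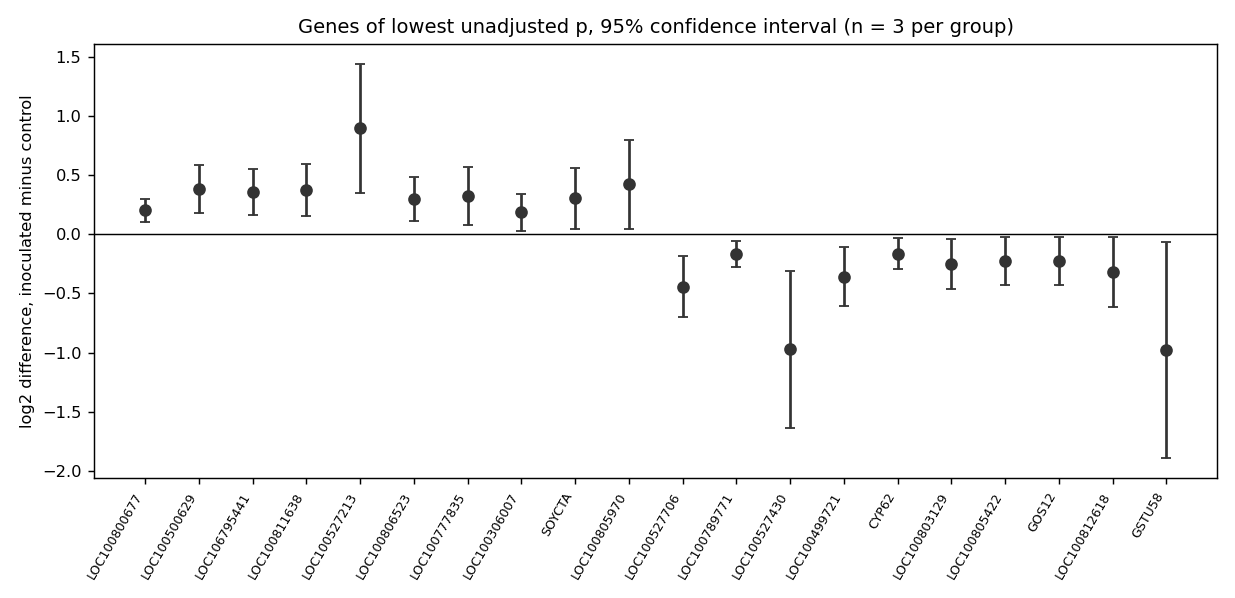
Log2 difference, rust-inoculated minus control, of the 10 higher and 10 lower genes with the lowest unadjusted p, each at 1 probe set. Points are group differences of 3 against 3 arrays and bars are 95% confidence intervals from limma. The differences run from -0.98 for GSTU58 to 0.90 for LOC100527213, and all adjusted p were 1.

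The array also carries 15820 probe sets for Phytophthora sojae and 7530 for the soybean cyst nematode Heterodera glycines, which give the background level in these leaves. Their median level was 4.35 and 4.37 in controls and in inoculated leaves alike, against 7.56 and 7.60 for soybean. The median difference over these probe sets was -0.000645 and 0 passed the threshold in limma, with 2 of each kind at an unadjusted p under 0.05.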

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

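The tests on control replicate 3, on its spread and on single lists below were chosen after the results were seen, and so were those on other splits of the arrays.

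A probe set made for the soybean cyst nematode stood out in data outside the main measurement because it was above background and higher in all 3 inoculated samples than in all 3 controls. Its log2 values were 6.555, 6.622 and 6.083 in controls and 6.875, 6.916 and 7.051 after inoculation, a difference of 0.528 with an unadjusted p of 0.0309 and an adjusted p of 1 in limma. Of 23350 probe sets for other organisms, 3 had all inoculated values above all controls and 13 had all below, where chance gives 5% each way. The probe set was picked for this separation, so its unadjusted p is no separate evidence. Which transcript it read in these leaves was not tested.

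Control replicate 3 stood apart from the other 5 arrays. Scaling between arrays is argued against, since after quantile normalization 8232 probe sets still lay more than 2-fold from the median of the others. At most 2057 did so on another array. Its spike controls bioB, bioC and bioD were the lowest of the 6 arrays, at 8.28, 9.49 and 12.43. The other arrays had 8.85 to 9.12, 10.30 to 10.54 and 12.855 to 13.085. A technical difference of this array therefore stays open as a part. Degraded RNA as the whole cause is argued against by 56 probe sets at background on the other 5 arrays and above a log2 value of 8 on this one (at most 2 on another array), but 347 went the other way (0 on the others), which degradation would also give, so it stays open as a part. The 3′ gaps went both ways, with actin the widest of the 6 arrays (2.32), GAPDH inside the others' range (0.583) and the GlutTrans and P450 controls the narrowest (-0.246 and 1.09). An exchange of labels with an inoculated array is argued against as the cause, since the other 5 arrays, of both groups, correlated at 0.959 or more with each other and this one at 0.863 to 0.877 with the inoculated arrays and at 0.845 and 0.858 with the controls. That cannot tell its group. It was closer to the inoculated arrays, with the pathogenesis-related list at 1.23 and the osmotin-like list at 1.37. With all 6 arrays neither list was called. Without this array, camera with the preset correlation called both higher after inoculation (medians 0.795 and 0.777, adjusted p 0.0108 and 0.000122). Both lay at -0.724 on rust-inoculated replicate 1. The lipoxygenase list at 0.251 goes with the control label, by its median without this array (-0.28). The heat shock list at -0.452 has the sign of the control label, by its median of 0.335 without this array. At percentile 13.64 it lay inside the range of matched random lists on this array (-0.656 to 0.172), so it cannot tell the group. Heat shock was mixed within groups, at 0.227 on control replicate 2 and -0.245 on rust-inoculated replicate 1. A single wrong label stays open, as do a sample from outside the series and a pot in another physiological state. No biological explanation was tested, since the design names none.

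No probe set passed the threshold, and the spread added by control replicate 3 is a possible explanation. Without that array the number stayed at 0. Shifts of 4-fold added to the remaining 5 arrays were recovered for 2.5% of probe sets, against 13% with all 6 arrays. Leaving it out thus did not raise recovery. It also lowered the number of arrays, so this trial cannot decide, and the explanation stays open. With array weights, which gave that array the lowest weight (0.173), the number was also 0. The 10 splits of the 6 arrays are too few for a share under 0.05. For probe sets past the threshold the comparison is void, since a real count of 0 is reached by all 10 whatever the data; the highest other count was 3. At an unadjusted p under 0.05, all 10 gave at least the 219 of the real split, and the highest other count was 3245. That split set control replicates 1 and 3 and rust-inoculated replicate 1 against the rest.

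For the lists called by camera, the same 10 splits are too few for a share under 0.05. The real split called 4 lists, 7 of the 10 splits called as many, and the highest other number was 6. For the lipoxygenase list 1 split of 10, the real one, gave an adjusted p as low as 3.73e-08, and the lowest of the others was 4.75e-05. For the heat shock list 2 of 10 gave one as low as 1.37e-07, and the lowest of the others was 1.74e-08. Camera adjusted p under 0.05 also came from other splits. For the lipoxygenase list they were 0.00387, 0.000227 and 4.75e-05, in the other splits that kept control replicates 1 and 3 together. For the heat shock list they were 0.0243, 1.74e-08, 0.0411, 0.0271 and 0.0295. The preset correlation thus called both lists on groupings other than the real one.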

How the results depend on the processing

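The fit without a pseudocount, the one on replicates 1 and 2 and the symbol lists were chosen after the data were seen. The count of probe sets past the threshold was 0 in every setting run, with and without the 2-fold condition, and the lowest adjusted p was 0.477, in the unmoderated test. All 380 values of named genes under 19 settings kept their direction, with adjusted p of 0.628 or more. These genes were chosen for low unadjusted p on the same arrays. Where groups do not overlap, leaving out an array cannot turn the sign, so the kept direction is no separate evidence. The number at an unadjusted p under 0.05 ran from 23 of 6029 averaged genes and 52 of 28773 probe sets with a mean above 5 to 2980 on replicates 1 and 2. Only this last count lay above the 1879.6 that chance gives over 37593 probe sets, and the next highest was 787, without control replicate 1. The cause of the differences between settings was not tested.

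Camera called 4 lists. It called 2 with averaged genes, 0 with an estimated correlation, 0 of the 31 symbol lists, and 4 to 7 with an array left out. Fry, which is a separate test and not a camera setting, called 0. The lipoxygenase and heat shock lists kept their call in all settings with the preset correlation. The aquaporin call also ended with array weights (0.231), and the Rubisco activase call with centring (0.204), the filters (0.0798 and 0.164), array weights (0.219), the trended prior (0.222) and pseudocounts of 1 (0.0556) or none (0.0605), as adjusted p. On replicates 1 and 2 both ended (adjusted p 0.813 and 0.32). Calls were gained there for pathogenesis-related (0.0294) and vegetative storage proteins (0.024), the latter, which shares LOXB1 with the lipoxygenase list, also with array weights (0.0117).

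The direction of the camera test turned for these list medians, and the cause was not tested. With array weights they were -0.0279 for phenylpropanoid enzymes, -0.0801 for flavonoid enzymes, 0.0242 for glutathione S-transferases and 0.00118 for P450s. On replicates 1 and 2 they were 0.00905 for phenylpropanoid enzymes, 0.0842 for glutathione S-transferases, -0.0030 for WRKY factors, -0.0703 for salicylate regulators, -0.0135 for aquaporins and -0.0164 for P450s. With an array left out, medians of the lists that turned ranged from -0.777 to 0.986 (pathogenesis-related), -0.223 to 0.116 (phenylpropanoid), -0.454 to 0.00442 (flavonoid), -0.281 to 0.0534 (glutathione S-transferases), -0.309 to 0.0122 (WRKY), -0.104 to 0.0574 (ethylene), -0.25 to 0.0612 (vegetative storage), -0.106 to -0.000178 (P450s) and -0.0400 to 0.00723 (root, nodule and seed).

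The other-organism median was -0.0270 with arrays centred, -0.0172 over probe sets with a mean above 5, and -0.00171 to 0.000708 with an array left out. With the replicate block 0 probe sets passed, 760 had an unadjusted p under 0.05 and 4 lists were called. Deviations of same-numbered arrays from their group means correlated at 0.318, 0.301 and -0.0145. Because those means include control replicate 3, these values cannot show that pairing is absent. As arrays, same-numbered replicates 1 and 2 correlated at 0.987 each across groups, against 0.962 between control replicates 1 and 2. Control replicate 3 did not correlate best with its own number. No label pairs the numbers, so the main fit kept no block, and whether they pair the arrays stays open. Signal over background limits dim probe sets, which the pseudocount compresses.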

Other observations

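The lists of symbols and the comparisons of single arrays here were chosen after part of the data had been seen, and none of the values on single arrays carries a test.

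Of the 31 symbol lists, 0 were called. The lowest adjusted p, 0.0751, was shared by GASA peptides (small cysteine-rich proteins linked to gibberellin; median 0.71, 14 of 20 probe sets higher after inoculation), histone and replication genes (0.63, 7 of 9 higher), receptor-like kinases (0.30, 17 of 22 higher) and enzymes and regulators of the allene oxide and jasmonate branch (-0.14, 16 of 21 lower). In the last of these, AOS2, an allene oxide synthase, differed by -0.40 (SE 0.22). The medians turned, without control replicate 3, to -0.17 for GASA peptides, -0.10 for histone and replication genes and -0.057 for receptor-like kinases, and the jasmonate branch was at -0.071 (adjusted p 0.133, 0.818, 0.983 and 0.705). Photosystem and light-harvesting genes had a median of 0.14, with 19 of 24 probe sets higher (adjusted p 0.114, and -0.070 at 0.339 without control replicate 3), and anthocyanin and flavonol enzymes had 0.064 (0.2). Osmotin-like, chitinase and glucanase genes had 0.097 (0.214), isoflavonoid and pterocarpan enzymes -0.02 (0.303), alternative oxidases -0.32 with 6 of 6 probe sets lower (0.238), SWEET sugar transporters -0.073 (0.214), and NAC factors -0.18 (0.195). MYB factors had -0.028 and bZIP factors -0.038, both at 0.195, and nodulins had -0.0025 (0.26). The remaining lists had adjusted p of at least 0.326. These were antioxidant enzymes (-0.024), chlorophyll and carotenoid genes (-0.017), ferritins (0.073), peroxidases (0.17), Kunitz and Bowman-Birk inhibitors (-0.034), wall proteins (0.059), clock genes (0.093), seed storage proteins (-0.00069), reference genes (-0.084), cyclophilins (0.064), heat shock factors (0.0033), calmodulins (-0.0011), glyoxalases (-0.0075), late embryogenesis proteins (-0.0017), DREB and ERF factors (-0.13) and sieve element proteins (0.014), each as a median log2 difference. With an estimated correlation 0 of the 31 were called, with adjusted p of at least 0.907. With the preset correlation, 5 of the 31 were called once control replicate 3 was left out. Osmotin-like, chitinase and glucanase genes (median 0.78, adjusted p 0.000122), heat shock factors (0.14, 0.00403) and isoflavonoid and pterocarpan enzymes (0.0014, 0.0117) were higher, and wall proteins (-0.29, 0.000101) and sieve element proteins (-0.31, 0.0125) lower.

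Control replicate 3 had a distinct set of abundant and scarce transcripts. GASA peptides lay at a median of -3.1 against the other 5 arrays, below all 10000 random lists matched on level, with 14 of 20 probe sets more than 2-fold below. GASA6 read 6.09 there and 11.33 to 13.24 on the others. Histone and replication genes lay at -2.11 (percentile 0.01), although H4 read 15.05, and wall proteins at -1.09 (percentile 0.01). Receptor-like kinases lay at -0.708 (percentile 0.34), peroxidases at -0.865 (percentile 0.11) and photosystem genes at -0.498 (percentile 4.78). ADR11, a transcript named for its response to auxin, was 134-fold below the median of the others. ALDH3J2, the aquaporin PIP2-1 and the fatty acid desaturase FAD3C were near background there, at 4.92, 4.43 and 4.81, with medians of 11.24, 10.43 and 10.68 on the others. Osmotin-like, chitinase and glucanase genes lay at 1.37, isoflavonoid and pterocarpan enzymes at 0.508, glutathione S-transferases at 0.581 and NAC factors at 0.446, each at percentile 100. Such percentiles were not particular to this array. The osmotin-like list was at percentile 100 on rust-inoculated replicate 2 (1.22) and at percentile 0 on control replicate 1 (-1.54). The proline-rich wall protein PRP1 and CIM1, named for its induction by cytokinin, read 11.61 and 10.58, with medians near background on the others, at 4.63 and 4.36. The Bowman-Birk inhibitor BBI-1 was 53.4-fold above the median of the others, the osmotin-like OLPa 35.2-fold and the sugar transporter SWEET17 32.7-fold. Seed storage proteins lay at 0.0126 and nodulins at 0.00922. Only 4 of 15 and 7 of 20 of their probe sets had a mean above background, so these medians say little about such transcripts. Of 37 late embryogenesis and maturation probe sets, 2 lay more than 2-fold above the others and 0 below. These were PM35 at 9.16 and MAT1 at 7.47, with medians of 5.11 and 4.57 on the others.

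Arrays of equal replicate number were alike for numbers 1 and 2. The correlation was 0.987 between control and rust-inoculated replicate 1 and 0.987 between control and rust-inoculated replicate 2, against 0.962 between control replicates 1 and 2. In the fit on these 4 arrays with both terms, 7296 probe sets had an unadjusted p under 0.05 for the replicate number and 2980 for inoculation, and 0 passed the threshold for either. Differences over 2-fold numbered 2057 and 297. Osmotin-like, chitinase and glucanase genes lay at -1.54 and -0.724 on the control and inoculated arrays of replicate 1 and at 0.266 and 1.22 on those of replicate 2. OLPb, an osmotin-like protein, read 8.20 and 10.27 on replicate 1 and 11.10 and 12.40 on replicate 2, control first.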
